A study of Mus musculus with 2 samples.

How the data were processed

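Single cell 3′ RNA libraries (10x Genomics) were made from 2 tumours of 4T1 mouse mammary carcinoma cells, 1 in the shCTL and 1 in the shHSF1 group. The values deposited by the authors are whole UMI counts per gene and barcode, without normalization. Per the submitters' processing notes, Cell Ranger 6.1 and genome build mm10 were used. The shCTL counts cover 32285 genes and 34956 barcodes already called as cells, with at least 500 UMIs in each. For the shHSF1 tumour the barcode list was counted, and its expression is not analysed here.

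Barcodes needed at least 200 detected genes and under 20% mitochondrial UMIs, which removed 16 and left 34940. Doublets were scored with a hand-written Scrublet-type score, with 2 simulated doublets per barcode. Its automatic threshold (0.872) marked 0 barcodes, so the highest 10% of scores were removed instead (3585 barcodes, score 0.208 or more, reached by 69.0% of simulated doublets); this was chosen after that outcome was seen. Counts of the 31355 barcodes kept were scaled to 10000 per barcode and log-transformed. The 2000 most variable genes among those in at least 10 barcodes were scaled, clipped at 10 and reduced to 30 principal components. A graph of 15 exact nearest neighbours with Jaccard weights was clustered by the Leiden method at resolution 1. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2, scikit-image 0.26.0 and matplotlib 3.10.9 were used.

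Cluster names were rebuilt here from 24 fixed marker lists and are not the authors' names. A name needed 20 or more cells, at least 3 markers with 10 or more UMIs above the median cluster, and the highest mean log2 level (pseudocount 10 CPM) or 2 markers among the 10 leading genes. A cluster with 10% or more of another lineage's marker level was set apart as mixed; this rule and its level were set after the data were seen. Clusters named T cell were clustered again with 1000 variable genes and 15 components. A part was named CD8 where Cd8a and Cd8b1 UMIs were at least 5 times those of Cd4. The naming of these parts was revised after its results were seen: an early version called a cycling Cd8a-positive part regulatory, and a later one named parts with 2 or more neutrophil or haemoglobin genes among the 10 leading genes or 10% or more of another lineage's marker level. That later version gave 708 CD8 T cell-like cells and a median log2 ratio of the exhaustion list between CD8 and 64 other T cells of 1.01 (0.24 to 1.24). The final rule leaves such parts without a name, so that ratio was not computed.

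UMIs were summed over the cells of a class and given as CPM with exact 95% Poisson intervals; shares have exact Clopper-Pearson intervals and ratios exact conditional binomial intervals. Cells of 1 tumour are not replicates, so no p-value was computed and no changed genes were counted over the genome. The gene lists and the rule for naming genes were set before the data were examined. The plan did not name the comparisons with macrophage-like cells. Its rule left out cell type markers, and leading genes, which come from these same data, were left out in addition. Text names Hsf1, Ccl5, Ccr1 and Ccr3, and from each of 18 gene lists the 2 members with the highest and the 2 with the lowest CPM ratio, among members with 20 or more UMIs that were neither markers nor leading genes of the classes compared. Some genes that this rule names, and the medians of a list that rest on them, are not reported here. Genes that describe a class were named as its markers or leading genes. A member counts as higher or lower where the ratio is at least 2 or at most 0.5 and the intervals do not overlap, and as between otherwise. Markers and leading genes of the classes compared are left out of these counts but not of the list medians, so the median over the counted members is given too where the sets differ; this was added after the data were seen. List medians use all members with 20 or more UMIs, a class at 0 set to 3 UMIs, and bounds from 1000 Poisson resamples. Each median was set beside 10000 random lists matched on mean expression. Ero1a was read under its synonym Ero1l. Gene positions are from GENCODE M21 (GRCm38).

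For the comparison by HSF1 target level, 6125 tumour epithelial-like cells with at least 1000 UMIs were thinned to that depth; 402 were too shallow. The thinning was first drawn a single time; as other draws gave other values, the median of 100 draws replaced it after that was seen. About 754 cells at the low and 680 at the high border share the same count, so their side was drawn at random.

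Calls were tested on simulated data drawn from the real class sizes. Both simulated classes were Poisson draws from 1 pooled profile, the model that the intervals assume. Real UMIs clump within cells and include RNA of other cells, which the simulation leaves out, so its rates are a best case. Against macrophage-like cells, 98% of genes raised 3 times were called in tumour epithelial-like, 80% in CD8 T cell-like, 76% in dendritic-like and 59.2% in neutrophil-like cells; 0.0806%, 0.386%, 0.675% and 0.737% of unchanged genes were called. Of genes lowered to 0.25 times, 100%, 48%, 55.1% and 42.9% were called in the same order of classes. Alternatives were other minimums of detected genes (500) and mitochondrial share (10%), no doublet removal, Leiden resolutions 0.5 and 2, 4000 variable genes, cells gated by marker UMIs, lists without Hspa1a, Hspa1b, Dnajb1 and Hsph1, and the highest and lowest 10% of cells. Purity levels, thinning depths, clusters and sets of cells were varied after the data were seen.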

Results

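Single cell RNA sequencing was run on tumours grown in mice for 3 weeks from 4T1 cells, a BALB/c mouse mammary carcinoma line. The series has 2 groups with 1 tumour each, so there are no replicates: shCTL tumours came from cells with a control hairpin RNA and shHSF1 tumours from cells with a hairpin RNA against Hsf1. Counts of unique molecular identifiers (UMIs) per gene were read for the shCTL tumour. Its 34956 barcodes held 62944617 UMIs, with 500 UMIs at the lowest, a median of 1289 and 15421 at the highest. For the shHSF1 tumour the list of 38143 barcodes was used, and its expression is not analysed here. All intervals are 95% intervals and cover counting error alone.

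The first question was which cells made up the control tumour, since the series title concerns CD8+ T cells kept out of breast tumours. Barcodes with keratins such as Krt8 and Krt18, named tumour epithelial-like, made up 20.8% of the 31355 barcodes kept (exact binomial interval 20.4% to 21.3%, 6527 barcodes). Macrophage-like cells, led by C1qa, Apoe and Mrc1, made up 17.5% (17.1% to 17.9%, 5483 barcodes). CD8 T cell-like cells, which carry the T cell receptor complex genes Cd3e and Cd3g and the coreceptor genes Cd8a and Cd8b1, made up 1.83% (1.69% to 1.99%, 574 barcodes); the share was 0% with at least 500 detected genes, 1.14% under 10% mitochondrial UMIs, 1.19% with 4000 variable genes and 3.37% without the purity rule. Conventional dendritic-like cells, led by Xcr1 and Clec9a, made up 1.06% (0.945% to 1.18%, 331 barcodes). Neutrophil-like cells, led by Ngp, S100a8 and S100a9, made up 0.759% (0.666% to 0.861%, 238 barcodes), but 0% with at least 500 detected genes, with 4000 variable genes or at a purity level of 5%, and 2.88% without the purity rule. NK cell-like cells with Ncr1 made up 0.102% (0.0698% to 0.144%, 32 barcodes), and T cell-like parts left without a finer name made up 0.631% (0.547% to 0.725%, 198 barcodes). The largest part, 57.3% (56.8% to 57.9%, 17969 barcodes), lay in clusters that held markers of more than 1 lineage and got no name. The largest mixed cluster, of 8272 barcodes with a median of 924 UMIs, had Igkc and the haemoglobin genes Hbb-bs, Hba-a1 and Hba-a2 among its leading genes. The next, of 3709 barcodes with a median of 730 UMIs, was led by Cdk8 and Cmss1. Fibroblast, endothelial, pericyte, B cell and plasmacytoid dendritic markers such as Col1a1, Cdh5, Rgs5, Cd79a and Siglech led some of the smaller mixed clusters, so shares of those types are not given. A further mixed cluster of 63 barcodes was led by the dendritic markers Ccl22 and Ccr7, and the dendritic-like share leaves it out. Among the 13383 named cells alone, tumour epithelial-like cells were 48.8%, macrophage-like cells 41.0% and CD8 T cell-like cells 4.29%.

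**Figure D1:**
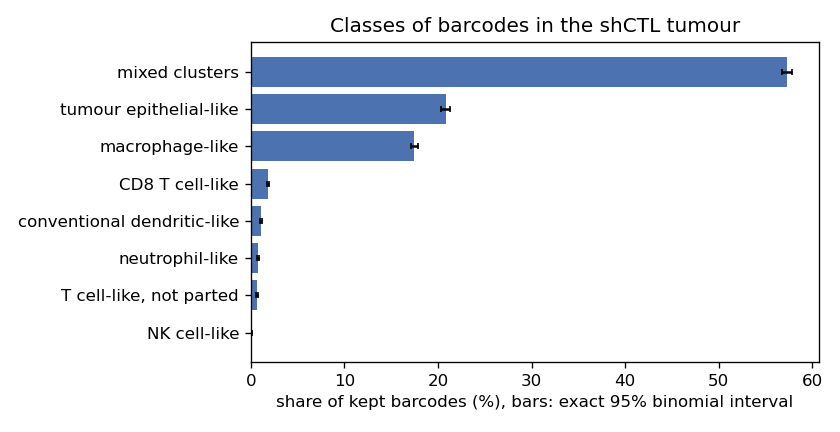
Share of kept barcodes (%, horizontal axis from 0) in each class of the shCTL tumour, with exact 95% binomial intervals as error bars. Mixed clusters held 57.3%, tumour epithelial-like cells 20.8%, macrophage-like cells 17.5% and CD8 T cell-like cells 1.83%.

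Of 804 barcodes in the clusters named T cell, 38.4% had a UMI of Cd8a or Cd8b1 (35.1% to 41.9%, 309 barcodes), at a median depth of 777 UMIs. Tumour epithelial-like cells, which should lack both genes, gave a background of 0.123% (8 barcodes) at a median of 2086 UMIs. With every barcode thinned to 500 UMIs, these shares were 26.5% and 0.0153%. Clusters with T cell RNA beside tumour markers had been set apart as mixed, so the tumour epithelial-like share is a floor and not the background of the library. A barcode without a Cd8a or Cd8b1 UMI is not thereby a cell without CD8.

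The next comparison asked how active the Hsf1 programme was in tumour cells of the control arm. Hsf1 encodes heat shock factor 1, which switches on chaperone genes. It lies on chromosome 15 from 76477422 to 76501913 (GRCm38, plus strand, ENSMUSG00000022556). In tumour epithelial-like cells Hsf1 was at 20.2 CPM (18.0 to 22.5, 321 UMIs), 1.30 times its level in all other named cells together (exact interval of the ratio 1.07 to 1.60). Most UMIs of these other cells were macrophage-like, with Hsf1 at 15.6 CPM (12.9 to 18.6). All classes among them were immune classes, since fibroblast and endothelial clusters were set apart as mixed. CD8 T cell-like cells had 19.5 CPM (9.37 to 35.9) and mixed clusters 18.5 CPM (16.8 to 20.3), near the tumour level. Single tumour clusters ranged from 14.8 to 22.5 CPM. Macrophage-like clusters of 4291, 792 and 352 cells had 14.5, 16.2 and 23.8 CPM (14.3 to 37.2 for the last), and 1 of 48 cells had 0 UMIs. The spread of clusters thus overlaps between both classes. Among the fixed list of HSF1 targets and chaperones, Serpinh1, which encodes the collagen chaperone HSP47, was 24.6 times as high in tumour epithelial-like cells (20.3 to 30.1), and Dnajb1, an HSP70 cochaperone, was 3.44 times as high (3.04 to 3.90). Hspa4 did not differ by the rule used (ratio 1.01, 0.947 to 1.07). Hspa1a was far lower (1.07 against 70.5 CPM, ratio 0.0151, 0.00877 to 0.0244). Hspa1a and Hspa1b encode almost the same HSP70 protein from near-identical sequences, so the split of reads between them is uncertain; Hspa1b was at 136 against 110 CPM. Of 19 members measured, 9 were higher, 1 was lower and 9 were between. The list's median log2 ratio was 0.94 (0.86 to 1.07), at percentile 99.8 of 10000 random lists of like expression, whose median was 0.21. Without the purity rule the list's median was 0.35 (0.33 to 0.40) and the Hsf1 ratio 1.14 (0.992 to 1.31), so that its interval no longer excluded 1. The immediate early genes that tissue dissociation can induce, such as Jun and Egr1, had a median of 0.92 (0.89 to 0.96), at percentile 98.9. Jun was 4.28 times (4.09 to 4.47) and Egr1 5.15 times as high (4.77 to 5.56), Zfp36 was between (0.765) and Nr4a1 lower (0.491).

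**Figure D2:**
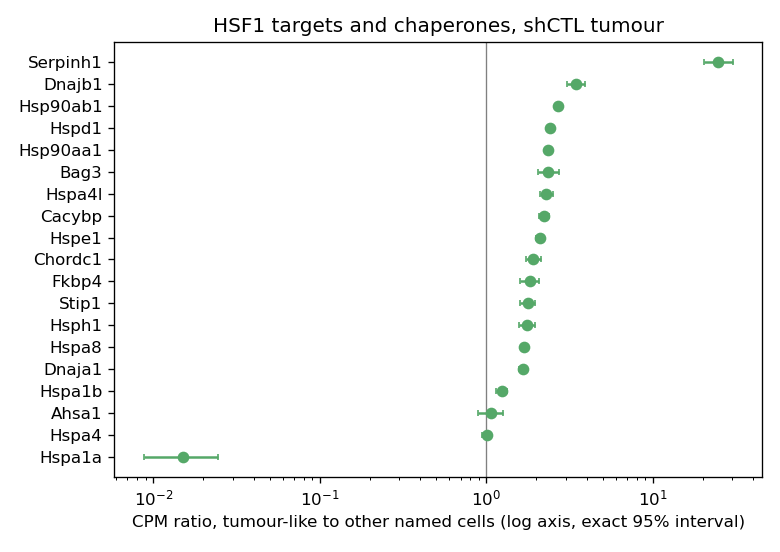
CPM ratio of tumour epithelial-like to all other named cells (log axis) for the 19 measured HSF1 targets and chaperones, with exact 95% intervals as error bars and a line at a ratio of 1. Serpinh1 is at 24.6, Dnajb1 at 3.44 and Hspa1a at 0.0151.

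Ccl5 was followed across classes because the series title names CCL5, a chemokine that draws T cells. The gene lies on chromosome 11 from 83525778 to 83530518 (GRCm38, minus strand, ENSMUSG00000035042). CD8 T cell-like cells had Ccl5 at 1064 CPM (977 to 1158) and NK cell-like cells at 1231 CPM (837 to 1748). Macrophage-like cells had 37.1 CPM (33.0 to 41.7), dendritic-like cells 54.8 CPM (34.3 to 82.9) and neutrophil-like cells 43.6 CPM (18.8 to 85.8). T cell markers in these 3 classes stood at 0.579%, 2.24% and 2.20% of their level in T cell-like cells. The same share of T cell Ccl5 is 5.23 CPM (4.5 to 6.0), 20.2 CPM (14.4 to 27.5) and 19.9 CPM (11.8 to 31.4), which for neutrophil-like cells overlaps the measured interval. These values rest on the mean Ccl5 of T cell-like cells. The T cell part of most Ccl5 per marker UMI would bring more, which was not computed here. An overlap for dendritic-like cells is therefore not excluded. The dendritic-like class leaves out a mixed cluster of 63 barcodes led by Ccl22 and Ccr7. With that cluster included, 394 cells had Ccl5 at 287 CPM, so the class level does not stand for all dendritic cells. Tumour epithelial-like cells had the lowest level of the named classes, 7.66 CPM (6.36 to 9.15); it was 25.4 CPM with cells gated one by one by marker UMIs and 3.97 CPM without the 10 cells of most Ccl5 UMIs. Of all 3293 Ccl5 UMIs, tumour epithelial-like cells held 3.70% (3.09% to 4.41%), macrophage-like cells 8.84% (7.89% to 9.86%), CD8 T cell-like cells 16.6% (15.3% to 17.9%) and mixed clusters 65.6% (63.9% to 67.2%). Among the 1133 Ccl5 UMIs of named cells, CD8 T cell-like cells held 48.1% (45.2% to 51.1%), macrophage-like cells 25.7% (23.2% to 28.3%) and tumour epithelial-like cells 10.8% (9.02% to 12.7%). In tumour epithelial-like cells the 122 Ccl5 UMIs lay in 64 of 6527 cells, and 10 cells held 59 of them, with up to 12 in a cell. UMIs of the same cell are not independent, and an interval from resampled cells was wider, 5.26 to 10.7 CPM.

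Receptors for chemokines were read in the same classes. Ccr1 (chromosome 9, 123962124 to 123968692, minus strand, ENSMUSG00000025804), which binds CCL5 and other chemokines, was at 768 CPM in neutrophil-like cells (646 to 906) and 506 CPM in macrophage-like cells (490 to 522). It was at 17.6 CPM in CD8 T cell-like cells (8.04 to 33.4) and 2.39 CPM in tumour epithelial-like cells (1.69 to 3.28). Ccr3 (chromosome 9, 124021972 to 124031689, plus strand, ENSMUSG00000035448), the eosinophil receptor, had 3 UMIs in macrophage-like cells and 2 in tumour epithelial-like cells. CD8 T cell-like cells had 0 Ccr3 UMIs, with an exact upper bound of 7.20 CPM.

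**Figure D3:**
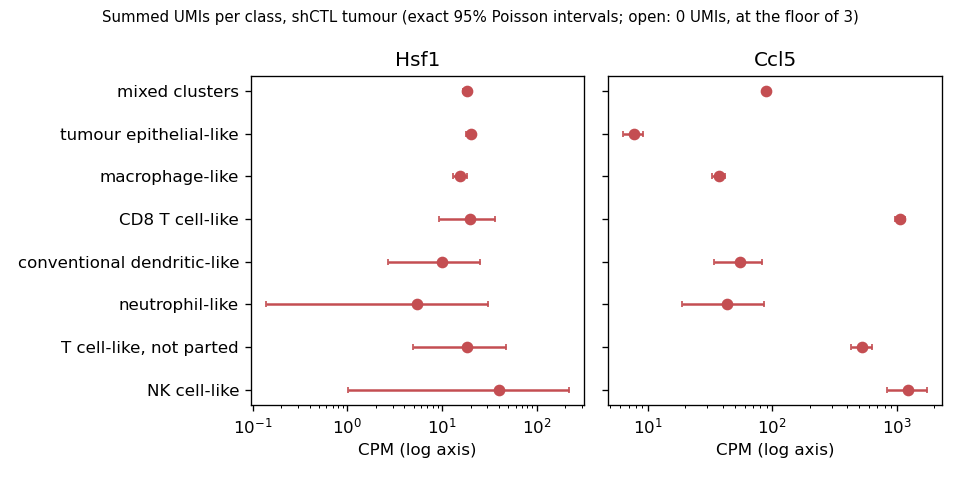
Summed CPM (log axes) of Hsf1 and Ccl5 in each class of the shCTL tumour, with exact 95% Poisson intervals as error bars. For Ccl5, CD8 T cell-like cells are at 1064 CPM and tumour epithelial-like cells at 7.66 CPM.

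Whether Ccl5 differed with the level of HSF1 target RNA inside tumour epithelial-like cells was asked next, since the series title names a suppression of CCL5. Cells were ranked by the share of their UMIs from the HSF1 targets and chaperones after thinning to 1000 UMIs, and the highest 2042 were set against the lowest 2042. The low and high cells had medians of 5 and 11 list UMIs at that depth. Counting error alone can spread counts about that far, so the ranking may hold little real difference in HSF1 target level. The Ccl5 ratio of high to low was 1.47 as the median of 100 thinnings, with median exact bounds of 0.934 and 2.38. Single thinnings ranged from 0.723 to 2.63; 39 had a lower bound above 1 and 0 had an upper bound under 1. The median bounds lie on both sides of 1, with a median of 31 Ccl5 UMIs in the low and 48 in the high cells, and with each cell counted a single time the ratio was 0.969. By cluster the ratio was 4.68 (1.88 to 13.2) in cycling cells led by Cenpf and Top2a, where it was 1.47 (0.432 to 5.45) with each cell counted a single time, and 0.601 (0.231 to 1.5), 0.564 (0.143 to 1.75) and 0.930 (0.0651 to 9.62) in the other tumour clusters. Without the cluster led by Cenpf and Top2a, the ratio over the other 4984 cells was 0.688 (0.338 to 1.34), with 17 Ccl5 UMIs in the high and 24 in the low cells. In that setting 0 thinnings had a lower bound above 1 and 19 had an upper bound under 1.

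Tumour epithelial-like cells were next compared with macrophage-like cells, the main immune class, for genes that draw or restrain other cells. Macrophage-like clusters held tumour markers at 1.99% to 4.64% of the highest cluster's level. Stray tumour RNA at such a share can make up the macrophage-like level of Csf3, so its ratio can be a lower bound. Chemokines that attract T cells were lower in tumour epithelial-like cells, with a list median log2 ratio of -5.49 (-5.66 to -4.33), at percentile 0.01 of random lists; 7 of 8 members were lower and 1 was between. Ccl3 and Ccl4 had ratios of 0.0113 (0.00751 to 0.0162) and 0.00651 (0.00487 to 0.00853). Cxcl10, an interferon-induced CXCR3 ligand, was at 103 CPM in tumour epithelial-like and 312 CPM in macrophage-like cells, and Ccl17 was between (ratio 1.48, 0.561 to 4.54). Factors for myeloid cells went both ways: Csf3, which encodes the granulocyte growth factor G-CSF, was 60.1 times as high in tumour epithelial-like cells (39.2 to 97.2) and Il34, a ligand of the macrophage receptor CSF1R, 23.8 times (14.3 to 42.8). Chemokines that draw neutrophils went both ways too: Cxcl2 and Cxcl3 were lower, at 0.0152 (0.0136 to 0.0169) and 0.0161 (0.00686 to 0.0322), while Cxcl1, at 1127 against 362 CPM, was 3.11 times as high (2.99 to 3.24) and Cxcl5 was at 36.2 against 0.766 CPM. Cxcl1 and Cxcl5 were named after their values were seen. Cxcl5 was also a leading gene of a tumour epithelial-like cluster in these same data. Its higher level is therefore no separate result, and it is not among the members counted. That list's median was 0.35 (0.29 to 0.41), at percentile 60.0, over 13 members; without the 4 that are markers or leading genes of these classes it was 1.64 (1.58 to 1.69), at percentile 99.7, with 5 members higher, 3 lower and 1 between.

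The immunosuppressive list, chosen for myeloid cells, and the checkpoint ligands were mostly lower in tumour epithelial-like cells. Genes of myeloid cells as a lineage are higher in macrophages than in tumour cells, so these ratios do not show which class restrains T cells. The immunosuppressive list had a median of -4.92 (-5.08 to -4.78), at percentile 0 of random lists, and -4.37 (-4.53 to -4.21) over the 11 members counted, of which 8 were lower and 3 between; Il1b and Il1rn were at 0.00603 (0.00531 to 0.00682) and 0.00516 (0.00294 to 0.00841), while Ptgs2, the prostaglandin enzyme COX-2, was alike at 707 and 599 CPM. Vegfa was between in both lists that hold it (0.641). Checkpoint ligands had a median of -2.97 (-3.08 to -2.86), at percentile 0.13, with 1 member higher, 5 lower and 2 between: Cd80 and Cd86 were at 0.00563 (0.00314 to 0.00932) and 0.00174 (0.00121 to 0.00244), Cd47 was between (1.45) and Nectin2 was 6.18 times as high in tumour epithelial-like cells (4.11 to 9.70). MHC class II genes had a median of -4.62 (-4.68 to -4.56), at percentile 0.14, and all 7 measured members were lower, with H2-Ab1 and Cd74 at 0.0327 and 0.0353 and H2-DMa and Ciita at 0.111 and 0.120. MHC class I presentation genes had a median of -0.34 (-0.37 to -0.28), at percentile 9.64: Tap1, a peptide transporter, was lower (0.379, 0.343 to 0.419), and the other 9 members, with Psmb8 at 1.07, Psmb9 at 0.626 and Nlrc5 at 1.73, were between. The BALB/c alleles of H2-K1 and H2-D1 differ from the reference sequence, which can lower their counts.

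Programmes inside the cells were compared for the same classes. Stray tumour RNA can make up much of the macrophage-like level of Twist1 and Snai1 (26 and 33 UMIs), so their ratios can be lower bounds. Mesenchymal genes can differ between macrophages and other cells as lineages, so these ratios do not show a transition of the tumour cells. Interferon response genes had a median of -1.30 (-1.48 to -0.98), at percentile 0.33 of random lists, and -0.96 (-1.03 to -0.88) over the 11 members counted, with Ifi27l2a at 0.0150 and Ifit2 at 0.189, Bst2 between (1.24) and Irf1 2.01 times as high in tumour epithelial-like cells (1.89 to 2.13); 1 member was higher, 5 lower and 5 between. NF-kB targets had a median of -0.81 (-0.85 to -0.76), at percentile 6.03, with Icam1 at 0.0241 and Il6 at 0.159, Nfkb1 and Nfkb2 between (1.40 and 1.51), 4 members lower and 4 between. Hypoxia and glycolysis genes had a median of 0.40 (0.21 to 0.48), at percentile 78.1, and 0.40 (0.19 to 0.52) over the 8 members counted; Egln3, a HIF prolyl hydroxylase, was at 133 against 10.2 CPM (interval of the ratio 10.4 to 16.5) and Eno1 2.04 times as high (1.85 to 2.26), Pgk1 was between (0.735), and 6 members in all were between. Proliferation genes had a median of 0.66 (0.54 to 0.81), at percentile 92.6, and 0.66 (0.47 to 0.78) over the 7 members counted, with Tpx2 higher (2.14, 1.87 to 2.47) and Cdk1, Pcna and Mcm5 among 6 members between (1.69, 0.913 and 0.986). Mesenchymal genes had a median of 2.55 (2.52 to 2.57), at percentile 99.99; Twist1 and Snai1, transcription factors of epithelial-mesenchymal transition, were 37.4 times (25.5 to 57.5) and 29.3 times as high (20.8 to 42.7), Zeb1 was between (0.673) and Zeb2, which macrophages express, was lower (0.182, 0.176 to 0.188). The HSF1 target list had a median of 0.98 (0.90 to 1.10, percentile 99.85) and the immediate early list 0.77 (0.73 to 0.81, percentile 95.03) against macrophage-like cells alone. In that comparison Serpinh1 was at 28.7, Dnajb1 at 3.54, Hspa4 at 180 against 184 CPM, Hspa1a at 0.0139, Jun at 3.98, Egr1 at 6.25, Zfp36 at 0.691 and Nr4a1 at 0.475.

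CD8 T cell-like cells were compared with macrophage-like cells over 512048 UMIs. Genes of T cells as a lineage are higher in any T cell than in macrophages, so these ratios do not tell T cell states apart. Macrophage-like cells held T cell markers at 0.579% of their level in T cell-like cells. Stray T cell RNA at that share can make up their level of Cxcr6 and Pdcd1, so the ratios of these genes can be lower bounds. Of the cytotoxic genes, Ifng, the T cell interferon, was at 248 against 0.255 CPM, where the lower level rests on 2 UMIs (ratio interval 264 to 8111). Fasl was 156 times (62.7 to 501) and Gzma 51.5 times as high (31.6 to 87.0), while Tnf was lower (0.261, 0.104 to 0.543). Of the list of exhaustion genes and inhibitory receptors, Pdcd1, which encodes PD-1, was at 279 against 1.02 CPM (ratio 274, 135 to 646), Cd160 at 64.4 against 0.255 CPM, where the lower level again rests on 2 UMIs, Nr4a2, which encodes a transcription factor, was 2.69 times as high (2.31 to 3.11) and Entpd1, which encodes the ectonucleotidase CD39, was between (0.698). The cytotoxic list had a median of 8.29 (7.81 to 8.85), which falls to 6.74 (5.86 to 7.72) without the 4 members that are markers or leading genes of these classes; of the other 5, 4 were higher and 1 was lower. The exhaustion list had 4.98 (4.30 to 5.24), and 2.96 (2.58 to 3.30) without 2 such members, with 7 higher and 1 between. Over all members both lists were at percentile 100 of random lists. Naive and memory genes had a median of 2.65 (2.45 to 3.25), also at percentile 100, and 2.60 (1.89 to 2.84) over the 5 members counted, with 4 members higher and 1 lower: Ccr7 was 41.1 times (22.7 to 78.2), Il7r 6.27 times (5.12 to 7.64) and S1pr1 2.95 times as high (1.40 to 5.69), and Klf2 was lower (0.225, 0.155 to 0.315). Of the receptors for other chemokines, Cxcr6 was 223 times as high (133 to 406), Ccr2 and Cxcr4 were lower (0.132 and 0.324), and the median was 0.48 (-1.46 to 1.69), at percentile 79.2. Ccr1 was lower than in macrophage-like cells (0.0348, 0.0159 to 0.0661). Of the T cell attracting chemokines, Ccl5 was 28.7 times as high (24.8 to 33.2), Ccl3 was between (1.24), Cxcl9 and Cxcl16 were lower (0.00899 and 0.0127), and the median was -0.02 (-0.21 to 0.14), at percentile 38.55, over 7 members and -2.88 (-3.39 to -2.28), at percentile 1.51, over the 6 counted. The planned ratio of the exhaustion list between CD8 and other T cells was not computed, because the part with the most Foxp3 and Cd4 UMIs (9 and 12) got no name.

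Neutrophil-like cells were compared with macrophage-like cells over 183630 UMIs. Nos2, whose product nitric oxide synthase can restrain T cells, was 13.9 times as high (9.90 to 19.1), Arg2 was between (1.58) and Il10 was lower (0.0796, 0.00201 to 0.445). Trem2, a macrophage receptor, had 0 UMIs, with an exact upper bound of 20.1 CPM, against 153 CPM in macrophage-like cells. Cxcl3 was 17.1 times (13.4 to 21.7) and Csf1 9.42 times as high (5.22 to 16.1), and Cxcl1 and Ccl7 were lower (0.120 and 0.0168). Egln3 and Ero1l, both induced by low oxygen, were 14.9 times (9.35 to 23.2) and 5.05 times as high (3.97 to 6.34), Pgk1 was between (0.852) and Vegfa lower (0.312, 0.188 to 0.489). Ccr1 was between (1.52, 1.27 to 1.80). Cd86 and Pvr were lower (0.0489 and 0.238), Cd47 was between (1.25) and Nectin2 had 0 UMIs against 25. Hypoxia and glycolysis genes had a median of 0.43 without Car9, which had 0 UMIs, and 0.94 (0.39 to 1.33) with Car9 set to 3 UMIs, against -0.58 in random lists (percentile 99.65); 4 members were higher, 1 lower and 7 between. The myeloid factors gave no direction as a list: the median was -2.12 (-2.45 to -1.69) over 10 members (percentile 0.42) and 2.23 (2.05 to 2.31) over the 7 counted (percentile 99.09), or -2.70 over these with Csf3, at 0 UMIs, put lowest. Of the 7, 3 were higher, 3 lower and 1 between. The immunosuppressive list, at -0.58 (-1.0 to -0.32) against -0.71 (percentile 59.4), and the checkpoint ligands, at -0.77 (-1.19 to -0.35) against -0.56 (percentile 37.7), were near random lists, though the latter was at -1.46 with its 2 members at 0 UMIs put lowest; 1 member was higher, 4 lower and 6 between in the former, and 3 lower and 5 between in the latter.

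Conventional dendritic-like cells, which present antigen to CD8 T cells, were compared with macrophage-like cells over 401814 UMIs. The mixed cluster of 63 barcodes led by Ccl22, Ccr7 and Ccl17, where most dendritic Ccl5 lay, is not among them. Psmb9, an immunoproteasome subunit, was 3.39 times (2.94 to 3.90) and Tap1 2.35 times as high (1.90 to 2.87), with H2-D1 and B2m between (0.773 and 0.720) and a class I median of 0.02 (-0.17 to 0.29), at percentile 36.7 of random lists. Ciita, the MHC class II activator, was 2.48 times as high (1.96 to 3.10), H2-Ab1, H2-DMa and Cd74 were between (1.63, 1.13 and 1.19), and the class II median was 0.64 (0.57 to 0.69), at percentile 79.4 of random lists, whose median was 0.38. Ccl17, which draws CCR4-positive T cells, was 111 times as high (45.9 to 322), from 34 UMIs in 15 of 331 cells against 6 UMIs in macrophage-like cells, Ccl5 was between (1.47, 0.910 to 2.28), Ccl3 and Cxcl10 were lower (0.231 and 0.0479), and the chemokine median was -1.09 (-1.29 to -0.91), at percentile 1.06, and -1.30 (-1.60 to -1.05) over the 7 members counted. Cd274, which encodes PD-L1, and Lgals9 were lower (0.385, 0.299 to 0.488, and 0.121), Cd47 and Nectin2 were between (1.30 and 1.56), and the checkpoint median was -0.10 (-0.67 to 0.16), at percentile 39.95. The interferon median was -1.13 (-1.58 to -0.67), at percentile 0.2, and -1.03 (-1.45 to -0.50) over the 11 members counted, with Oasl2 lower (0.0709) and Ifit1 and Irf7 between (0.163 and 0.876).

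The shHSF1 tumour was compared with the shCTL tumour by the number of barcodes alone, 38143 against 34956, a ratio of 1.09. This count says nothing about the share of CD8 T cells or the level of Ccl5 in either arm.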

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

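The tests of mixed barcodes and of immune RNA below were all chosen after the results were seen, the second tests of even free RNA and of immune RNA because of the outcome of the first, a further test of immune RNA after both others, and the second test of a common pool after a trial with similar genes had been seen.

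Mixed clusters, singled out because they enter no comparison between classes, held 2160 Ccl5 UMIs (89.1 CPM, 85.4 to 92.9), and Ccl5 was among the leading genes of a mixed cluster of 476 barcodes with Cd3e and Trac beside tumour markers and of another of 358 barcodes with Trac beside macrophage markers.

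Barcodes with tumour and macrophage RNA together made up 49.2% of those kept (15437), and mixed barcodes of any kind were 78.8% of those with 500 to 800 UMIs and 42.3% of those with 3000 or more. Macrophage marker UMIs per barcode with tumour markers were 1.21 times as many at 2000 or more UMIs as under 1000 (1.17 to 1.25), which goes with free RNA spread evenly over droplets, but tumour epithelial-like cells held 0.188 such UMIs each against 5.35 in these barcodes (ratio 0.0351, 0.0331 to 0.0371), which argues against it, since under an even Poisson level the poorest 20.8% of barcodes would hold 2.36. Whole pairs of a tumour cell and a macrophage do not account for most of these barcodes, whose median of 922 UMIs was 0.260 times that of summed random pairs (quartiles 0.214 to 0.363). A common pool of free RNA stays open: in the largest such cluster the spread between barcodes was 1.25 times binomial with the fixed markers (median 7 UMIs), under the bound of 1.5 set for a pool, and 3.49 times with 149 tumour and 278 macrophage genes (median 76 UMIs), above the bound of 2 against it, where simulated draws stayed at or under 1.06. Both values lay above the simulated draws, and a bound of 1.5 is hard to pass at 7 UMIs per barcode, so the first test decides little. The second goes against a single pool in that cluster. Igkc and haemoglobin genes were among the leading genes of that cluster, which free RNA of further cell types could give, and this was not tested. These values come from 1 library, so a pool was not told apart from damaged cells or partial mixing, and no biological explanation was tested.

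Ccl5 UMIs in tumour epithelial-like cells, 7.66 CPM with a lower bound of 5.26 from resampled cells, could be RNA of immune cells in the same droplets. Summed markers of T cells, macrophages, neutrophils and dendritic cells would bring 15.1 CPM, but 13.1 CPM of it came from dendritic markers (394 cells at 287 CPM of Ccl5, a mixed cluster of 63 included; with the 331 dendritic-like cells alone the sum is 4.67 CPM), where Fscn1 had 2352 of 2646 UMIs and stood at 81.4% of its dendritic level against 0.0226% for Clec9a and 0.0138% for Ccl22, so the sum does not measure dendritic RNA and decides nothing. With the median marker of each source, immune RNA would bring 2.51 CPM (up to 3.09), which goes against it, although the level was 3.97 CPM without the 10 cells of most Ccl5 UMIs. Cells without a T cell marker UMI still had 6.76 CPM. Only 143 such UMIs lay in the 6527 cells, so few cells were left out and this value decides nothing. With the T cell part of most Ccl5 per marker UMI and with NK cells as a further source, immune RNA would bring 5.11 CPM (up to 6.06). That upper bound passes the lower bound of 5.26. The source of these UMIs therefore stays open, expression by tumour cells included.

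The lists of the shHSF1 and shCTL tumours share 387 barcodes (1.11% of the shCTL list), singled out because the shHSF1 list enters no comparison of expression, and the shared barcodes had a median of 1265 UMIs in the shCTL tumour against 1289 for the others.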

How the results depend on the processing

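Purity levels, naming of T cell parts without the rule on other lineages, thinning settings, counting each cell a single time, leaving out the cluster of cycling cells and the Ccl5 levels in subsets of tumour epithelial-like cells were tests chosen after the results were seen. Of 85 values under an alternative, 59 stayed inside the interval of the reported value and 26 left it. The purity settings left the tumour epithelial-like class unchanged. Its share, its Ccl5 level, its share of Ccl5 UMIs and its Ccl5 ratio by HSF1 target level were therefore identical under them. These values count among the 59 but test nothing. For ratios with a reported interval that excludes 1, 0 alternatives turned the direction.

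The share of tumour epithelial-like cells was 21.9% with at least 500 detected genes, 18.9% both without doublet removal and at Leiden resolution 2 (18.90% and 18.93%), 19.5% under 10% mitochondrial UMIs, 19.7% with 4000 variable genes and 17.6% with cells gated by tumour markers. The share of CD8 T cell-like cells was 0% with at least 500 genes, 1.61% without doublet removal, 1.29% and 1.27% at resolutions 0.5 and 2, 1.14% under 10% mitochondrial UMIs, 1.19% with 4000 genes, 3.37% without the purity rule, 1.37% at a purity level of 5%, 1.66% with cells gated by Cd3 and Cd8 UMIs, and 2.26% with T cell parts named without the rule on other lineages. Neutrophil-like cells were 0% with at least 500 genes, with 4000 genes and at a purity level of 5%, and 2.88% without the purity rule. At 0% no cluster got the name. The cause was not tested.

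The HSF1 target list's median stayed within 0.88 to 1.07 except without the purity rule, where it was 0.35; that setting counts mixed barcodes with tumour RNA among the other cells. The Hsf1 ratio ranged from 1.14 to 1.31, and at 1.14 its lower bound was 0.992. Ccl5 in tumour epithelial-like cells was 9.45 CPM with 4000 genes, 25.4 CPM with cells gated one by one and 3.97 CPM without the 10 cells of most Ccl5 UMIs; its share of all Ccl5 UMIs was 4.43% with 4000 genes. The cause was not tested, apart from the 10 cells, whose removal is itself the change. The Ccl5 ratio of high to low HSF1 target level was 0.688 without the cluster of cycling cells, and otherwise ranged from 0.969, with each cell counted a single time, to 2.19 in the first thinning, where its bounds were 1.30 and 3.80. The exhaustion list ratio of CD8 to other T cells had no value in the reported setting or under any alternative to the clustering, filters or purity level. No paired analysis was possible because each group has 1 tumour. Depth limits the classes with few UMIs most: in simulated data 59.2% of genes raised 3 times and 42.9% of those lowered to 0.25 times were called in neutrophil-like cells.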

Other observations

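The tests of the HSF1 target list and of Ccl5 by HSF1 target level were written before their results were seen; the use of 100 thinnings and the values by cluster, without a cluster and with each cell counted a single time were tests chosen after.

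In tumour epithelial-like cells Hspa1a was at 1.07 CPM and Hspa1b at 136 CPM, while macrophage-like cells had 77.1 and 112 CPM. No explanation was tested.

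The higher HSF1 target RNA of tumour epithelial-like cells could come from stress during tissue dissociation or from proliferation. The other named cells were all immune classes, so a difference between lineages could give it too and was not tested. Without Hspa1a, Hspa1b, Dnajb1 and Hsph1, the list's median log2 ratio was 1.07 (1.0 to 1.13) against 0.94 for the whole list, but leaving out any 4 of the 19 members could not have brought it under 0.83, above the bound of 0.47, so this decides nothing. The immediate early list was high as well, with a median of 0.92, and dissociation stays open. Without the cluster of cycling cells led by Cenpf and Top2a, the median was 0.97 (0.86 to 1.07), which argues against that cluster as the cause. Higher HSF1 activity in tumour cells is a hypothesis that a single control tumour does not test.

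A hypothesis that Ccl5 is lower where HSF1 target RNA is high was tested inside tumour epithelial-like cells. The ratio of 1.47 (0.934 to 2.38) has bounds on both sides of 1 and gave no answer. The ranking could hardly have given one, since low and high cells had medians of 5 and 11 list UMIs. Counting error alone can spread counts about that far. With each cell counted a single time the ratio was 0.969. The cluster of cycling cells had a ratio of 4.68 (1.88 to 13.2), but UMIs of the same cell are not independent, and with each of its cells counted a single time the ratio was 1.47 (0.432 to 5.45), from 8 high and 5 low cells. Without that cluster the ratio was 0.688 (0.338 to 1.34).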
